A study of Trichodesmium erythraeum IMS101 with 19 samples.

How the data were processed

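DNA methylation was measured by whole-genome bisulfite sequencing in Trichodesmium erythraeum IMS101, a filamentous marine cyanobacterium that fixes nitrogen. Per the labels' protocols, cells were filtered and flash frozen at midday, and DNA was extracted with a kit for soil. The DNA was then bisulfite treated with the Zymo Gold kit, made into libraries with the NuGEN Ovation Ultra-Low Methyl-Seq kit and sequenced on an Illumina NextSeq. The authors deposited 1 table of methylation levels as a fraction between 0 and 1 for 798 genome positions in 19 libraries. No value was missing, and fractions were multiplied to percent here. The aligner, the methylation caller, the genome build, the coverage filter and the rule by which these 798 positions were chosen are not given in the sources used here. The table carries no read counts, so the depth behind each level is unknown, no counting interval could be given, and differences were judged against the spread between libraries only.

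Groups were taken from the labels. The founding ancestral population had 1 library, listed at 380 µatm CO2. Lines selected at 380 or 750 µatm CO2 had 3 libraries each after 4.5 years and 3 each after 7 years. At 4.5 years there were also 3 libraries from 380 lines kept at 750 µatm for 2 weeks and 3 from 750 lines kept at 380 µatm for 2 weeks. The labels call these libraries biological replicates. No sequencing batch or date is given, so a batch that follows the groups could not be told apart from CO2 or year.

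The positions run from 43908 to 7702000 with no chromosome, strand or gene name. They were matched to the RefSeq gene table of assembly ASM1426v1, used only for gene names because the build behind the positions is not named. The numbering match was tested. Of the 798 positions, 693 (86.8%) fell inside genes, against a mean of 512 in 10000 circular shifts of the positions along the genome, of which 0 gave as many. After shifts of 100 bases the count was 671 in one direction and 677 in the other, so a match of the numbering to the single base is not shown. The positions lay in 367 genes, of which 355 were protein-coding, 11 pseudogenes and 1 a tRNA gene. A gene symbol was available for 44 of these genes, and the others are named by locus tag. The positions formed 212 adjacent pairs. Sequence context (CG, CHG or CHH) was not analysed here because it needs the genome sequence.

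Levels in percent were tested per position with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean for each of the 6 replicated groups (18 libraries), moderated variances with a mean trend and robust estimation, two-sided tests, and Benjamini-Hochberg adjustment over the 798 positions. A position was called at an adjusted p below 0.05. The comparisons were 750 against 380 at each year, each transfer against its source line, 7 against 4.5 years in each line, selection history and current CO2 as main effects of the 4.5-year groups, and the interaction of CO2 with year. Errors of limma differences are standard errors, and errors of group levels are standard deviations over libraries. Each standard error uses a variance per position shared by all 6 groups, so groups outside a comparison can also widen or narrow it. Mean levels per library were compared by exact two-sided permutation tests, adjusted over 8 comparisons, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6. With 3 libraries against 3 these exact tests cannot go below p = 0.1. Whether CO2 differences were shared between years was tested by relabelling libraries within each year. Positions in 12 gene lists, matched by gene symbol, were compared with all other positions by Fisher's exact test where a list held at least 3 positions.

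The comparisons, tests, gene lists and alternatives were fixed before the data were examined, as was the rule for naming positions. That rule takes, per comparison, up to 12 called positions with the largest rise and 12 with the largest fall among those whose libraries did not overlap between the groups. For the interactions no such overlap was scored, so positions were named there without this condition. Where there were under 5 calls the rule takes the 5 positions of smallest p. It also takes the called position of smallest p in each gene list, and for the ancestral library the 5 positions farthest outside the other libraries. The test planned for read counts could not be used, because only fractions were held, so the test planned for levels was used. A comparison of each transferred group with the lines already at its new CO2 and the interaction of history with current CO2 were added after the data were seen.

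Tried as alternatives were arcsine and log2-ratio scales (offset 0.01), positions with a mean level of 10 to 90 percent (752 positions), a difference of at least 10 points, quantile normalisation over the 18 libraries, a fit on the compared libraries only, limma with no trend, replicate number as a block, averaging of adjacent positions, and leaving out each library in turn. The limma step was tested on simulated data, levels with 598 unchanged positions and the rest changed by a known amount. For 750 against 380 at 4.5 years it recovered 10% of changes of 5 points, 26% of 10 points, 80% of 20 points and 92% of 30 points, with 3 false calls. For 750 against 380 at 7 years it recovered 4%, 44%, 86% and 98%, with 7 false calls. For the down-transfer the shares were 6%, 26%, 74% and 98% with 2 false calls, and for the interaction of CO2 with year 0%, 18%, 64% and 82% with 4. These shares and false calls describe the simulated levels only. Real levels shift together over whole libraries, and their spread differs between groups. At 4.5 years the SD of mean levels between libraries was 0.432 points in 750 lines and 7.47 in down-transferred cultures. The false calls therefore do not give the error rate in the real libraries.

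Because levels differed between libraries at nearly every position, each comparison is given as deposited and relative to its median difference, with the result after quantile normalisation, which gives all 18 libraries 1 distribution of levels. Comparisons against the same libraries share their chance values, so overlaps of calls are given with the number expected of independent lists and the mean of 50 simulations with no effect. Such simulations make hardly any calls, so neither number is a no-change value for lists that share libraries. Figures were drawn with matplotlib 3.10.9.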

Results

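The data are methylation levels at 798 genome positions in 19 bisulfite libraries of Trichodesmium erythraeum IMS101. The labels describe cultures that descend from 1 founding population and were selected at 380 or 750 µatm CO2 for 4.5 or 7 years. Short transfers of 2 weeks were made in both directions at 4.5 years. Below, 380 lines and 750 lines are the selected cultures in their own CO2, the up-transferred cultures are 380 lines moved to 750 µatm, and the down-transferred cultures are 750 lines moved to 380 µatm. The comparisons ask whether methylation differed with long selection, whether it moved with a short change of CO2, and whether the differences lasted to 7 years. Sequencing depth per position is unknown, and gene names rest on a numbering match to RefSeq assembly ASM1426v1, since the build behind the positions is not named.

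The founding population, listed at 380 µatm CO2, carried the highest methylation of all libraries, with a mean level of 65.7% over the 798 positions. The 380 lines at 4.5 years averaged 40.0% ± 1.43 (SD, n = 3) and the 750 lines 18.4% ± 0.432 (n = 3). Up-transferred cultures averaged 18.3% ± 4.79 (n = 3) and down-transferred cultures 27.3% ± 7.47 (n = 3). At 7 years the 380 lines averaged 38.8% ± 2.65 and the 750 lines 34.2% ± 2.49 (n = 3 each). Replicate 3 stood apart in both transferred groups. Its mean level was 23.8% in the up-transferred group, where replicates 1 and 2 had 16.1% and 14.9%, and 35.9% in the down-transferred group, where the others had 22.9% and 23%.

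**Figure D1:**
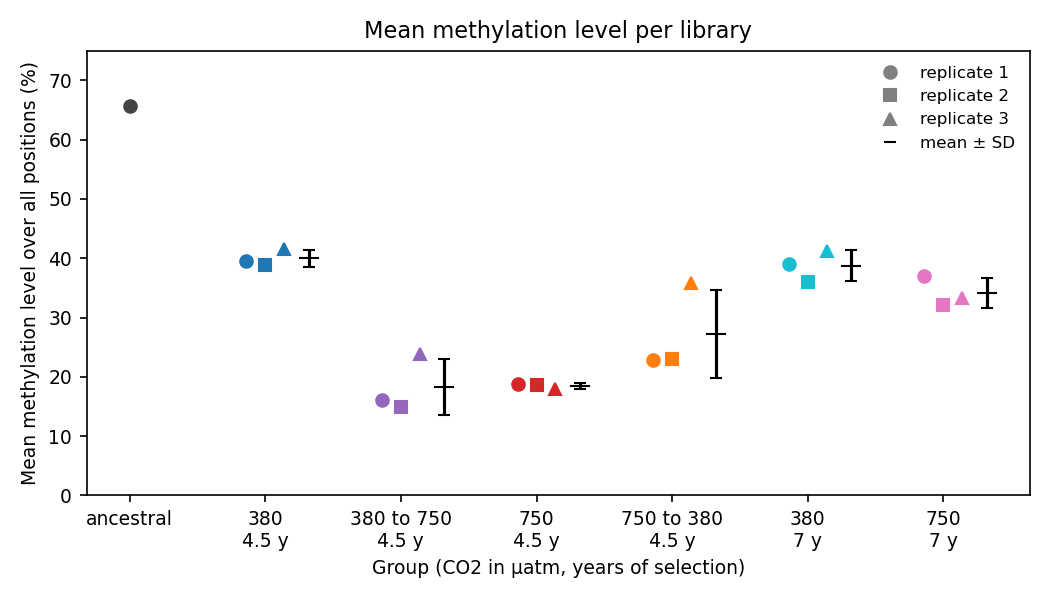
Mean methylation level (percent, y axis) of each library over all 798 positions, by group (x axis), with replicates 1, 2 and 3 as circles, squares and triangles and the group mean ± SD beside them. The ancestral library stands at 65.7%, the 380 lines at 40.0% and 38.8%, and the 750 lines at 18.4% after 4.5 years and 34.2% after 7 years.

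Ancestral levels lay above all 18 other libraries at 774 positions and below them at 0, so that 97.0% of positions were outside the range of the others, where chance gives 10.5% if positions were listed without regard to their ancestral level. The listing rule is not given, and the ancestral library had 0 positions under 20%, where the others had 73 to 597. Its adjacent positions correlated at 0.249, against 0.678 to 0.907 in the others. Its levels also spread less over positions (SD 10.2 points, against 13.2 to 17.4), and a narrower spread lowers such a correlation at equal noise. The SD within adjacent pairs was 8.17 points against 3.95 to 8.98, and it holds lasting differences between paired positions as well as noise. The widest gap was at 2423251, between genes, with 67.1% in the ancestral library and at most 14.3% in any other. TERY_RS34840 (2673750) had 68.3% against at most 18.2%, TERY_RS15985 (5121080) 63.4% against at most 16.8%, and TERY_RS16635 (5311334) 61.0% against at most 17.1%. The fifth position of this kind, 6808832, lies between genes and had 66.9% against at most 23%. Positions in TERY_RS16665 went the other way: at 5349222 the ancestral library had 22.3% and the 380 lines at 4.5 years 48.2% ± 4.59 (n = 3). The ancestral population had 1 library, so these differences have no replicate check and no test.

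After 4.5 years of selection, methylation was lower at 750 than at 380 µatm at nearly every position, and it was higher in a small set of positions led by TERY_RS15250 and dnaJ. At 4861393 in TERY_RS15250 the level was 18.8% ± 2.43 (SD, n = 3) in 380 lines and 90.4% ± 4.55 (n = 3) in 750 lines, a difference of 71.6 ± 17 points (SE, adjusted p = 0.00126). This SE also takes in the up-transferred libraries, outside this comparison, which ranged from 11.8% to 91.0% at 4861393. Its neighbour at 4861392 had 18.9% and 87.7%. In dnaJ (TERY_RS08190), which encodes a co-chaperone of DnaK, 2669238 had 53.0% ± 3.51 in 380 lines and 89.2% ± 2.78 in 750 lines, a difference of 36.2 ± 4.69 points (adjusted p = 5.07e-06), and 2669239 was higher by 27.1 ± 4.97 points. The single ancestral library had 83.2% at 4861393, 76.4% at 4861392, 88.9% at 2669238 and 89.4% at 2669239. At these positions the 380 lines lay farther from the ancestral level than the 750 lines did. The largest fall was in TERY_RS00515, where 178865 had 55.1% ± 5.92 in 380 lines and 4.75% ± 1.75 in 750 lines (-50.3 ± 6.85 points, adjusted p = 5.07e-06).

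The other positions higher in 750 lines were 6632404 between genes (30.1% against 61.4%), 5974640 and 5974641 in the tRNA gene TERY_RS18570 (26.5 and 30.1 points), 6280037 in TERY_RS19550 (33.8% against 53.6%), 2212728 and 2212729 in TERY_RS32610 (19 and 19.4 points), 6007734 in TERY_RS18660 (22.3% against 38.5%) and 43908 in the pseudogene TERY_RS29450 (65.6% against 79.6%). The ancestral library had 54.1% (6632404) to 80.5% (43908) at these other positions, above every 380 library of 4.5 years. A higher level in 750 lines is thus not by itself a gain over the founding population. Among the other large falls, 178864 in TERY_RS00515 fell by 47.5 points and 5349221 in TERY_RS16665 went from 51.1% ± 2.75 to 5.49% ± 1.66. Position 5349222 in TERY_RS16665 fell by 43.9 points, 3837190 in TERY_RS36870 by 41.6, 4787090 in TERY_RS14990 by 41.6, 5118901 in TERY_RS15975 by 41.5, 6593077 in TERY_RS20620 by 40.7 and 4007886 in TERY_RS33010 by 40.7. Between genes, 7526886 fell by 47.2 points, 2679554 by 45.7 and 2679555 by 43.1.

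Of the gene lists fixed beforehand, 4 held any listed position and 8 held none, among them those for photosynthesis, carbon fixation, DNA methyltransferases and mobile elements. Only 44 of the 367 genes with a position had a symbol to match. A list without positions may thus have members named by locus tag alone, and absence of its function is not shown. All 4 positions of the nitrogen list were lower in 750 lines. In nifD (TERY_RS19890), which encodes the alpha subunit of the molybdenum-iron nitrogenase protein, 6381990 had 80.3% ± 4.22 in 380 lines and 54.2% ± 0.81 in 750 lines (adjusted p = 2.34e-05). The others were 1258563 and 1258564 in hypF (-27.1 and -28.8 points) and 1265166 in hypE (-18.1 points, but 7.66 after quantile normalisation), both genes of hydrogenase maturation. All 3 positions of the phosphorus list were lower. In phnG (TERY_RS24105), a gene of phosphonate breakdown, 7639452 had 52.8% ± 6.08 and 18.5% ± 3.58, and in phnE, a phosphonate transporter gene, 7638322 had 59.0% and 29.3% and 7637980 had 10.6% and 1.62% (0.86 points higher after quantile normalisation). Both dnaJ positions, which made up the stress list, were higher. Of the translation list, 4652171 in rplE was lower by 20 points (28.5% against 8.49%, but 0.71 points higher after quantile normalisation) and 5018912 in rpsN was not called (35.9% against 31%). Adjusted over the list alone, the calls were 4 of 4 nitrogen, 3 of 3 phosphorus, 2 of 2 stress and 1 of 2 translation positions. In 18 Fisher's exact tests of lists against the other positions over all comparisons, for the 2 lists with at least 3 positions, the smallest adjusted p was 0.598, and for calls of at least 10 points it was 0.231. Where nearly all positions or none were called, such a test could show no excess of calls in a list, so these values leave open whether a list stood apart there.

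In this comparison limma called 790 of 798 positions, 12 higher and 778 lower in 750 lines. Positions may have been listed because they differ between these lines, which could have raised this count. The mean level per library differed by -21.5 points (exact permutation p = 0.1, the smallest that 3 against 3 allow, adjusted p = 0.16), and libraries of the groups did not overlap at 796 positions, where chance gives 10% per position if positions were listed without regard to this difference. The listing rule is not given, and levels shift together over whole libraries, so the 796 positions are not separate evidence. The median difference was -21.6 points. Relative to it, 4861393 in TERY_RS15250 was higher by 93.2 points, 2669238 in dnaJ by 57.8 and 2669239 by 48.7, while 178865 in TERY_RS00515 stood at -28.7, nifD at -4.53, phnG at -12.7 and rplE at 1.57. After quantile normalisation limma called 125 positions, 72 higher and 53 lower. These included all 12 positions higher as deposited and 53 of those lower, while 55 positions lower as deposited were then higher. The TERY_RS00515 and nifD positions were still lower after quantile normalisation (-30.7 and -13.7 points, adjusted p = 0.00475 and 0.0297). The calls at 5349222 in TERY_RS16665, 2679555, hypF and phnG and at phnE 7638322 ended (adjusted p = 0.0704, 0.104, at least 0.592, 0.096 and 0.289). The direction turned in rplE, hypE and phnE 7637980, none of them called then, and rpsN was called higher (19.4 points).

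**Figure D2:**
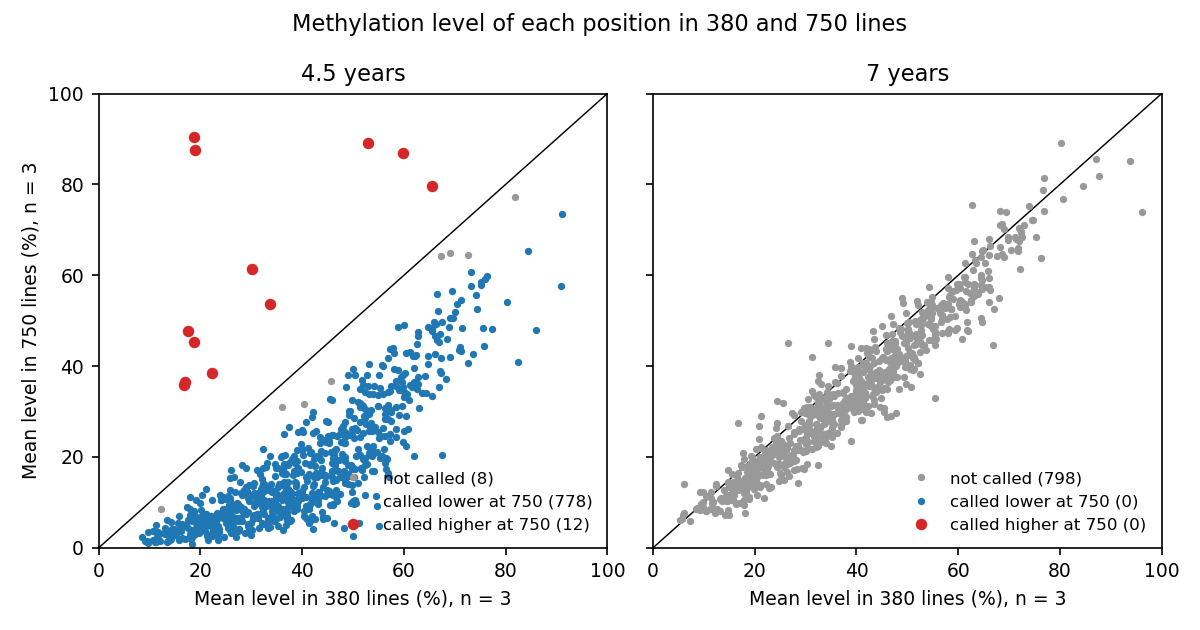
Mean level of each of the 798 positions (percent, n = 3 per mean) in 380 lines (x axis) and 750 lines (y axis), at 4.5 years on the left and 7 years on the right, with the line of equal levels. At 4.5 years 778 positions were called lower and 12 higher in 750 lines, and at 7 years 0 were called.

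After 2 weeks at 750 µatm the up-transferred 380 lines had lower levels than the 380 lines they came from at nearly every position, and higher levels in dnaJ. Position 2669238 in dnaJ had 53.0% ± 3.51 in 380 lines and 82.2% ± 4.57 after transfer (29.1 ± 4.69 points, adjusted p = 1.63e-05, n = 3 each), and 2669239 rose by 23.5 ± 4.97 points. Among the falls, 2679555 between genes went from 54.5% to 13.1% ± 9.34 and 2518933 in TERY_RS07690 from 73.6% ± 2.97 to 34.0% ± 15.3. The pseudogene TERY_RS25240 held several of the largest falls, with 3821902 at -37.3 points, 3822179 at -37.0 and 3822178 at -36.6 (44.9% ± 3.76 to 8.31% ± 8.49, adjusted p = 9.07e-06). At 178865 in TERY_RS00515 the mean fell by 39.3 points, but replicate 3 kept 40.9% where replicates 1 and 2 had 3.66% and 2.84%.

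Further positions that fell by 36 to 38 points were 178864 in TERY_RS00515, 5349221 in TERY_RS16665, 2679554 between genes, 3083569 in TERY_RS09345, 3837190 in TERY_RS36870 and 5118901 in TERY_RS15975. TERY_RS15250 differed between the replicates of this group. Position 4861393 had 89.5% and 91.0% in replicates 1 and 2 and 11.8% in replicate 3, against 16.1% to 20.7% in 380 lines, and its call (45.3 ± 17 points, adjusted p = 0.0203) came with overlapping libraries. All 4 nitrogen positions fell, with 1258563 in hypF at -27.0 ± 5.11 points and nifD at -23.6, as did all 3 phosphorus positions, with phnG at -32.6 ± 5.27, and both translation positions, with rplE at -19.1 and rpsN at -14.2, though rplE, rpsN, hypE, 1258564 in hypF and 7637980 in phnE turned direction after quantile normalisation (2.67, 11.7, 1.69, 2.60 and 2.27 points). These counts were the same when adjusted over the list alone (4, 3, 2 and 2 positions, with both dnaJ positions higher).

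Limma called 791 positions after the up-transfer, 5 higher and 786 lower, and the mean level per library differed by -21.7 points (exact permutation p = 0.1, the smallest possible, adjusted p = 0.16). The higher count was 2 without up-transferred replicate 1 or 2 and 11 without replicate 3. The 5 higher positions were the pairs in dnaJ and TERY_RS15250 and 5974640 in TERY_RS18570 (14.3 points, adjusted p = 0.0253), and all 5 were among the 12 positions higher in 750 lines, where independent lists would share 0.075 and simulations with no effect, which make hardly any calls, 0. Likewise 778 positions were called lower in both comparisons, where independent lists would share 766 and simulations with no effect 0. Both comparisons use the same 3 libraries of 380 lines, too few to divide, so part of the overlap may come from them, and neither value serves as its no-change value. Relative to the median difference of -22.4 points, dnaJ 2669238 rose by 51.5 points, 3822178 in TERY_RS25240 stood at -14.2 and rplE at 3.29. Quantile normalisation gave 9 calls, 6 higher and 3 lower. Of the 6, as deposited 2 had been called higher and 2 lower, and all 3 had been called lower. The dnaJ positions (41.1 and 34.4 points), 3822178 and 2518933 stayed called, the other named falls lost their call, and TERY_RS15250 and TERY_RS18570 lost their calls with their direction kept (adjusted p of at least 0.0535).

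Up-transferred 380 lines and 750 lines were then compared directly. No position was called by limma (0 at an adjusted p below 0.05, 30 at an unadjusted p below 0.05, smallest adjusted p = 0.219), and 1 position was called after quantile normalisation. The position of smallest p was 6830165 in TERY_RS21405, with 46.8% ± 1.43 after transfer and 64.8% ± 4.22 in 750 lines (n = 3 each). Next came 6632404 between genes (40.6% ± 17.8 against 61.4% ± 0.53), 6089812 in TERY_RS25710 (33.8% ± 1.90 against 52.1% ± 2.22), 43908 in TERY_RS29450 (66.0% ± 8.63 against 79.6% ± 0.56) and 2819119 between genes (51.4% against 64.2%). The mean level differed by -0.177 points (exact permutation p = 1). Without replicate 3 of the transferred groups, 1 position was called, 6830165 in TERY_RS21405 (-17.6 points, adjusted p = 0.0466).

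**Figure D3:**
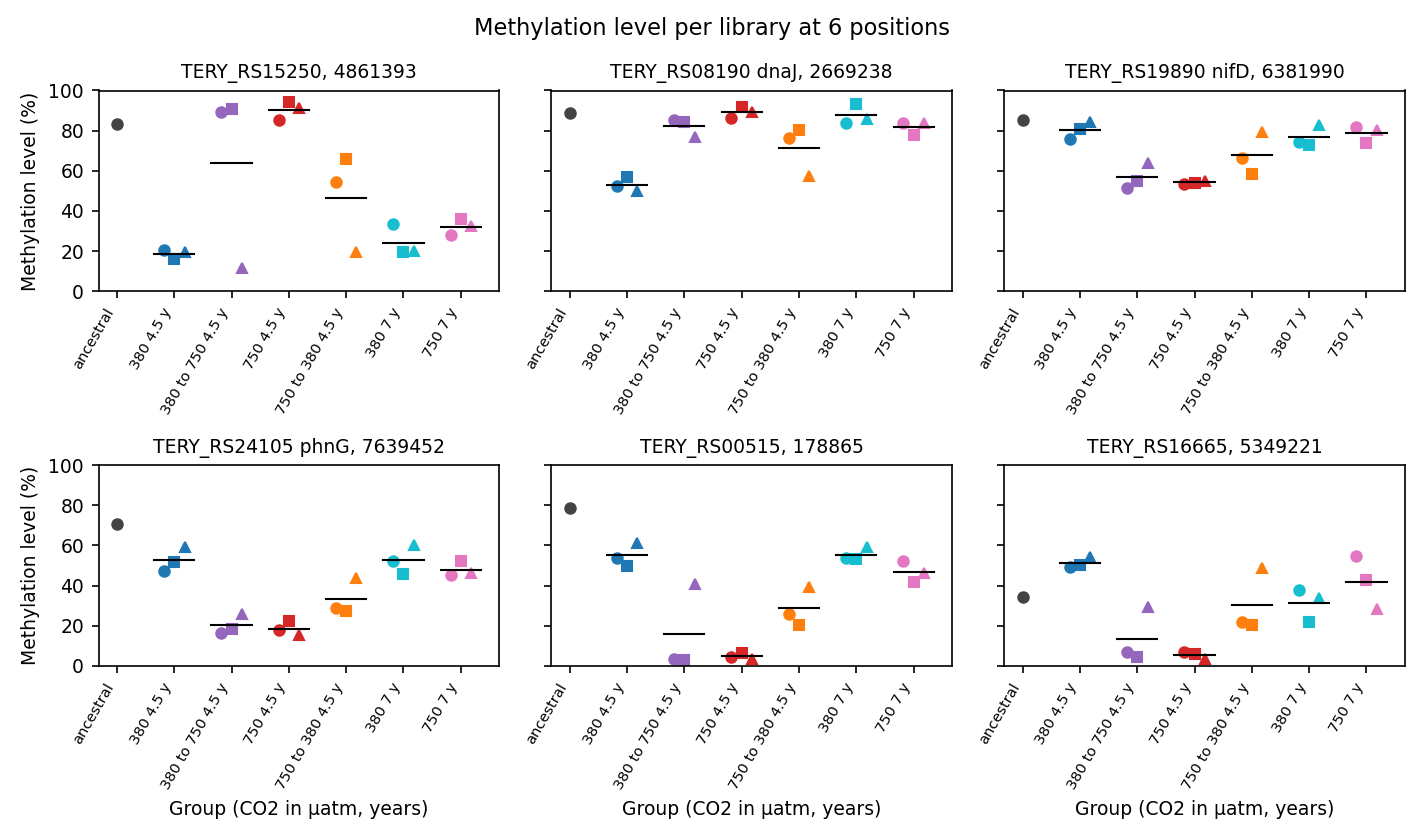
Methylation level (percent, y axis) of each library by group (x axis) at 4861393 in TERY_RS15250, 2669238 in dnaJ, 6381990 in nifD, 7639452 in phnG, 178865 in TERY_RS00515 and 5349221 in TERY_RS16665, with circles, squares and triangles for replicates 1, 2 and 3 and black lines for group means. In dnaJ the 380 lines at 4.5 years lie between 50% and 56.9%, and all other libraries except down-transferred replicate 3 (57.3%) lie at 76.1% or above.

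After 2 weeks at 380 µatm the down-transferred 750 lines had higher levels than 750 lines at most positions. Limma called 41 positions, against 248 on the arcsine and 289 on the log2-ratio scale. Position 3822178 in the pseudogene TERY_RS25240 rose from 6.63% ± 1.19 to 33.3% ± 7.08 (26.7 ± 5.17 points, adjusted p = 0.0126, n = 3 each), and 3821903 in the same gene by 21.9 points. In TERY_RS16665, 5349221 rose from 5.49% ± 1.66 to 30.3% ± 16.0, and in TERY_RS00515, 178865 rose from 4.75% ± 1.75 to 28.6% ± 9.61. Against this direction, 6632404 between genes fell from 61.4% ± 0.53 to 36.6% ± 5.22, 6280037 in TERY_RS19550 from 53.6% ± 1.72 to 32.7% ± 5.46 and 2669238 in dnaJ from 89.2% ± 2.78 to 71.2% ± 12.2. These 3 were the only called falls, and all 3 were among the 12 positions higher in 750 than in 380 lines (0.045 expected of independent lists, 0 in simulations with no effect), a comparison that uses the same 3 libraries of 750 lines with the opposite sign, so part of this overlap may come from them. Such simulations make hardly any calls, so neither value serves as its no-change value.

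Other rises of 21 to 28 points were at 2679554 and 3216833 between genes and in TERY_RS36870, TERY_RS14990, TERY_RS15975, TERY_RS26060 and TERY_RS02480. In the gene lists 0 of 4 nitrogen positions passed (nifD 54.2% to 68.1% ± 10.6, adjusted p = 0.0543), 0 of 3 phosphorus and 0 of 2 translation positions passed, and 1 of 2 stress positions fell. Adjusted over the list alone, 3 nitrogen, 1 phosphorus, 2 stress and 0 translation positions passed. Of the 41 positions 38 were higher and 3 lower, out of 372 at an unadjusted p below 0.05. The mean level was higher by 8.81 points (exact permutation p = 0.1, the smallest possible, adjusted p = 0.16). The size rested largely on down-transferred replicate 3, since without it the median difference over positions was 4.12 points. Relative to the median difference of 8.65 points, TERY_RS25240 3822178 rose by 18 points and dnaJ 2669238 stood at -26.6. Quantile normalisation gave 12 calls, 5 higher and 7 lower, of which 4 and 0 had been called in that direction as deposited, and of the positions named here the calls kept were TERY_RS25240 3822178 and TERY_RS14990 4787091. This count rested on single libraries: 0 positions passed without down-transferred replicate 3 or without any 1 of the 750 lines' replicates, and 300 or 299 passed without down-transferred replicate 1 or 2.

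Down-transferred cultures were lower than 380 lines at most positions. In TERY_RS00515, 178864 had 22.1% ± 15.1 after transfer and 50% ± 2.28 in 380 lines (-27.9 ± 6.73 points, adjusted p = 0.00626, n = 3 each), and 178865 was lower by 26.5 points. Also lower were 3822179 in TERY_RS25240 (-25.8 points), 3806365 in TERY_RS11800 (-22.5), 6593076 in TERY_RS20620 (-22.2), 5349222 in TERY_RS16665 (-22.1), 1396495 in TERY_RS04140 (-22.0), 3175741 in TERY_RS36665 (-21.8) and, between genes, 7526886, 3281735, 3216832 and 599895. The dnaJ positions were higher, 2669238 with 71.2% ± 12.2 against 53.0% ± 3.51 and 2669239 by 14.2 points. Limma called 656 positions, 2 higher and 654 lower, and the mean level differed by -12.7 points (exact permutation p = 0.1, the smallest possible). Relative to the median difference of -13.0 points, dnaJ 2669238 stood at 31.1 and TERY_RS00515 178864 at -14.9. Quantile normalisation left 1 call, dnaJ 2669238 (adjusted p = 0.0361). The count was 332 without replicate 3 of the 380 lines, and 131 and 12 without down-transferred replicates 1 and 2. Without down-transferred replicate 2 all positions named here lost their call except 3806365 in TERY_RS11800 (dnaJ 2669238 13.7 points, adjusted p = 0.0558).

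Whether levels followed the CO2 at sampling or the CO2 of selection was asked over the 4 groups of 4.5 years. By current CO2, mean levels were lower over the 6 libraries sampled at 750 than over the 6 sampled at 380 µatm. The libraries did not overlap at 114 of 798 positions, and their mean levels did overlap, with 23.8% in up-transferred replicate 3 and 22.9% in down-transferred replicate 1. In TERY_RS25240, 3822178 had 6.63% and 8.31% in groups sampled at 750 µatm and 44.9% and 33.3% in those sampled at 380 µatm, a difference of -31.6 ± 3.66 points (adjusted p = 1.1e-06). In TERY_RS26060, 7562372 differed by -26.9 points and 7562510 by -25.0, and in TERY_RS33010, 4007806 by -26.3. Position 4304245 in TERY_RS13310 differed by -25.9 points, 5105823 in TERY_RS25525 by -24.3, 4802678 in TERY_RS15055 by -23.6, 5628599 in TERY_RS17615 by -23.6, 1310912 in TERY_RS03905 by -23.5, 1716493 in TERY_RS05100 by -23.3, 5910043 in TERY_RS18410 by -23, phnG by -23.7 and hypF 1258563 by -20.5. The same 12 positions as in the comparison of 750 with 380 lines were higher at 750 µatm, with 44.5 ± 12 points at 4861393 in TERY_RS15250 and 23.5 ± 3.31 at 2669238 in dnaJ.

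For current CO2 limma called 795 positions, 12 higher and 783 lower, including 4 of 4 nitrogen, 3 of 3 phosphorus, 2 of 2 stress and 1 of 2 translation positions, with the same numbers when adjusted over the list alone. The mean level was 18.4% ± 3.05 at 750 and 33.6% ± 8.47 at 380 µatm (SD, n = 6 each), a difference of -15.3 points (exact permutation p = 0.00649, adjusted p = 0.052). This difference averages unlike parts, since the up-transfer lowered the mean level (-21.7 points) by more than the down-transfer raised it (8.81 points). Relative to the median difference of -15.3 points, 3822178 in TERY_RS25240 stood at -16.3 and dnaJ 2669238 at 38.8. After quantile normalisation 108 positions were called, 58 higher and 50 lower. Of the 58, as deposited 12 had been called higher and 43 lower, and all 50 had been called lower. The TERY_RS25240 and dnaJ positions stayed called, as did 4007806 in TERY_RS33010 and the positions in TERY_RS17615, TERY_RS05100 and TERY_RS18410, while those in TERY_RS13310, TERY_RS25525, TERY_RS15055, TERY_RS03905, phnG and hypF 1258563 and 7562372 in TERY_RS26060 did not, and rplE, hypE, hypF 1258564 and phnE 7637980 turned direction (2.25, 3.25, 0.31 and 1.72 points), and rpsN was called higher (12 points).

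By selection history, 750-selected cultures had lower levels than 380-selected cultures at 95 positions that passed the test. The called list positions were phnE 7637980 (-4.09 ± 1.32 points, adjusted p = 0.045), rplE (-7.18 ± 2.42, adjusted p = 0.0499) and dnaJ 2669238, which was higher (12.6 ± 3.31, adjusted p = 0.0443). The other higher positions were 2212728 in TERY_RS32610 (10.3 points) and 6632404 between genes (13.7 points). Limma called 98 positions, 3 higher and 95 lower, of 406 at an unadjusted p below 0.05, and at none of them were the 6 libraries of one history apart from the 6 of the other. In the lists 1 of 3 phosphorus, 1 of 2 stress and 1 of 2 translation positions passed, and 3, 2 and 1 adjusted over the list alone. The mean level differed by -6.28 points (exact permutation p = 0.316, adjusted p = 0.361) and the median over positions by -6.33. The mean-level value averages unlike parts. Down-transferred cultures differed from 380 lines by -12.7 points, and up-transferred cultures from 750 lines by -0.177. No position was called on the arcsine or log2-ratio scale, after quantile normalisation, or without any 1 of 9 of the 12 libraries, while 190, 275 and 634 were called without up-transferred replicate 1, up-transferred replicate 2 and down-transferred replicate 3. With replicate number as a block 329 were called.

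At 7 years no position was called between 750 and 380 lines. The position of smallest p was 3651449 in TERY_RS11270, with 18% ± 4.02 in 380 lines and 7.73% ± 1.90 in 750 lines (-10.3 ± 2.21 points, adjusted p = 0.0525, n = 3 each). Next were 1716492 in TERY_RS05100 (46.0% ± 10.5 and 28.7% ± 5.01), 4248837 in TERY_RS13145 (96.2% ± 0.7 and 73.9% ± 10.8), 3243818 between genes (22.8% and 13.1%) and 3087847 in TERY_RS09350 (46.9% and 29.1%), each with an adjusted p of 0.29. TERY_RS15250 4861393 had 24.3% ± 7.82 in 380 lines and 32.2% ± 4.2 in 750 lines, dnaJ 2669238 had 87.6% ± 4.96 and 81.9% ± 3.37, nifD 76.7% ± 5.54 and 78.7% ± 4.04, and phnG 52.7% ± 7.16 and 48% ± 3.80. Limma called 0 positions at an adjusted p below 0.05 and 106 at an unadjusted p below 0.05, and quantile normalisation also gave 0. Libraries of the lines did not overlap at 143 of 798 positions, where chance gives 10% per position, among them the positions named first. Levels shift together over whole libraries, so the share can lie far from 10% by chance. Of the lists 0 positions passed, and adjusted over the list alone 1 nitrogen position did. The mean level differed by -4.60 points (exact permutation p = 0.2, adjusted p = 0.267), and the median over positions was -4.60 as well. TERY_RS11270 3651449 passed without replicate 2 or 3 of the 380 lines or replicate 3 of the 750 lines (adjusted p = 0.0446, 0.0457 and 0.0353), and TERY_RS13145 4248837 passed on the log2-ratio scale, in the fit on these 6 libraries only and without replicate 3 of the 750 lines.

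The CO2 difference at 4.5 years and that at 7 years were compared position by position. Levels were lower in 750 lines at 786 positions at 4.5 years and at 692 at 7 years, and at 687 in both, while 7 were higher in both. With nearly all positions lower at 4.5 years, the overlap of 687 is expected even of unrelated differences. The 687 positions therefore do not by themselves show a lasting difference. That reasoning does not cover the positions higher in 750 lines, 12 at 4.5 years, 106 at 7 years and 7 in both. Whether these 7 exceed chance was not tested. Across positions, which are not independent replicates, the differences of the years had Pearson r = 0.26 (permutation p = 0.06, over 400 relabellings of libraries within year) and Spearman rho = 0.226 (permutation p = 0.07). Without replicate 1 of the 750 lines at 4.5 years r was 0.263 (permutation p = 0.04), without that at 7 years 0.309 (permutation p = 0.03), and without 7-year 750 replicate 2 it was 0.147 (permutation p = 0.18). No call was made at 7 years, so 0 calls were shared.

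Levels in 750 lines were higher at 7 than at 4.5 years at most positions, and a single position was called in 380 lines. In 750 lines, 3837191 in TERY_RS36870 rose from 22.3% ± 2.21 to 65.6% ± 8.00 (43.3 ± 7.05 points, adjusted p = 7.85e-05, n = 3 each), 178865 in TERY_RS00515 from 4.75% ± 1.75 to 46.9% ± 5.38, 7562372 in TERY_RS26060 from 14.1% ± 3.19 to 55.2% ± 13.8 and 2900751 in TERY_RS08900 from 6.42% ± 0.61 to 44.3% ± 6.42. Against this, 4861392 in TERY_RS15250 fell from 87.7% ± 0.44 to 29.1% ± 3.79 (-58.6 ± 16.3 points, adjusted p = 0.00587) and 4861393 by a similar -58.2 points. In 380 lines that position was 2669238 in dnaJ, which rose from 53.0% ± 3.51 to 87.6% ± 4.96 (34.6 ± 4.69 points, adjusted p = 2.75e-05).

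Other rises in 750 lines were at 5118902 in TERY_RS15975 (41.0 points), 5349222 in TERY_RS16665 (40.9), 4787090 and 4787091 in TERY_RS14990 (38.8 and 37.5), 3822041 in TERY_RS25240 (38.0) and 3952473 between genes (37.5). Other falls were at 6632404 between genes (-28.6 points), 6280037 in TERY_RS19550 (-24.1), 2212729 and 2212728 in TERY_RS32610 (-17.7 and -16.2) and 43908 in TERY_RS29450 (-11.1). All 7 falls were among the 12 positions higher in 750 than in 380 lines at 4.5 years, where independent lists would share 0.105 and simulations with no effect 0. Both comparisons use the same 3 libraries of 750 lines at 4.5 years with opposite sign, so part of this overlap may come from them. Neither value therefore serves as its no-change value. In the lists, nifD rose by 24.5 ± 4.75 points, phnG by 29.5 ± 5.27 and rplE by 12.3 ± 3.42 (-1.74 after quantile normalisation). Of the nitrogen list 3 of 4 positions rose, with 1258563 in hypF turning to -0.76 points after quantile normalisation, all 3 phosphorus positions rose, 1 of 2 translation positions rose and 0 of 2 stress positions passed, with the same numbers adjusted over the list alone.

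For the years, limma called 664 positions in 750 lines, 657 higher and 7 lower at 7 years, and 1 position in 380 lines, of 42 at an unadjusted p below 0.05. The mean level was higher by 15.7 points in 750 lines (exact permutation p = 0.1, the smallest possible, adjusted p = 0.16) and differed by -1.22 points in 380 lines (exact permutation p = 0.5, adjusted p = 0.5). Relative to the median difference of 15.3 points in 750 lines, TERY_RS36870 3837191 rose by 27.9 points, TERY_RS00515 178865 by 26.8, nifD by 9.14 and phnG by 14.2, while rplE stood at -3.04 and TERY_RS15250 4861392 at -74.0. Relative to that of -1.25 points in 380 lines, dnaJ 2669238 rose by 35.8. Quantile normalisation gave 153 calls in 750 lines, 71 higher and 82 lower. All 71 had been called higher as deposited, but of the 82 only 7 had been called lower, 2 had been called higher and the others not called. In 380 lines it gave 1 call, dnaJ 2669238. All called list positions of the 750 lines lost their call, with adjusted p of 0.0777 for nifD, 0.0533 for phnG, 0.0558 and 0.999 for phnE, 0.886 and 0.300 for hypF and 0.680 for rplE. Of those not called as deposited, hypE turned direction (-11.1 points) and rpsN was called lower (-18.8 points, adjusted p = 0.00353). In 380 lines the count was 2 without replicate 1 or replicate 3 at 7 years, with 2679555 between genes and 4006140 in TERY_RS33010 as the added positions (-36.2 and -13.6 points), and 5 in the fit on the libraries of this comparison only.

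The change of the CO2 difference between years was tested as an interaction. The largest positive value was in TERY_RS16665, where 750 minus 380 lines went from -43.9 points at 4.5 years to a level of 45.2% ± 17.5 against 26.5% ± 8.85 at 7 years for 5349222 (62.6 ± 11.7 points, adjusted p = 0.00121, n = 3 per group), and 56.4 ± 9.88 points for 5349221. Position 178864 in TERY_RS00515 changed by 44.9 points, 2518933 in TERY_RS07690 by 43.4, 2900751 in TERY_RS08900 by 43.0, 6839593 in TERY_RS25825 by 41.0, 4007886 in TERY_RS33010 by 40.7, 3837190 in TERY_RS36870 by 40.0 and 535739 in TERY_RS01590 by 39.3. Negative changes were found at 4861393 in TERY_RS15250 (-63.7 ± 24.1 points, adjusted p = 0.0352) and 2669238 in dnaJ (-41.9 ± 6.63, adjusted p = 0.000476), and smaller ones in TERY_RS18570, TERY_RS18660, TERY_RS19550, TERY_RS32610, TERY_RS29450 and at 6632404. In the lists nifD changed by 28.1 ± 6.71 points, phnE 7637980 by 10.6 ± 2.64 and rplE by 18.2 ± 4.84, with 2 of 4 nitrogen, 3 of 3 phosphorus, 2 of 2 stress and 1 of 2 translation positions called, the same when adjusted over the list alone.

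Limma called 541 positions for this interaction, 530 positive and 11 negative, of 594 at an unadjusted p below 0.05, and the mean level interaction was 16.9 points. Of 400 relabellings within year 38 were as large (permutation p = 0.095), but relabelling also takes away the CO2 difference at 4.5 years, so it does not test the interaction by itself. Relative to the median of 16.7 points, 5349222 in TERY_RS16665 stood at 45.8, TERY_RS15250 4861393 at -80.4, dnaJ 2669238 at -58.7 and rplE at 1.42. Quantile normalisation gave 15 calls, 8 positive and 7 negative, of which 8 and 3 had been called in the same direction as deposited and the other 4 not called. Calls kept were at 5349221 in TERY_RS16665 and dnaJ 2669238 (adjusted p = 0.00846 each). The calls at 178864 in TERY_RS00515 and in TERY_RS07690, TERY_RS08900, TERY_RS33010, TERY_RS01590, TERY_RS18660 and TERY_RS29450 also held. Those at 5349222 in TERY_RS16665, in TERY_RS25825, TERY_RS36870, TERY_RS15250, TERY_RS18570, TERY_RS19550 and TERY_RS32610, at 6632404, at 2669239 in dnaJ and at every called nitrogen, phosphorus and translation position ended (adjusted p from 0.0630 in TERY_RS25825 to 0.930 in rplE). The TERY_RS15250 4861393 call also ended without any 1 of 10 of the 12 libraries (adjusted p up to 0.0696), those in TERY_RS18570, TERY_RS19550, TERY_RS29450 and at 2212728 in TERY_RS32610 each ended without at least 1 library (adjusted p up to 0.0733), and 360 positions were called without replicate 3 of the 380 lines at 4.5 years. The standard error at 4861393 also took in the up-transferred libraries (11.8% to 91.0%), which are outside this interaction.

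Within groups, libraries correlated across positions at a mean r of 0.968 in 380 lines, 0.972 in 750 lines, 0.830 in up-transferred and 0.899 in down-transferred cultures at 4.5 years, and of 0.899 in 380 lines and 0.909 in 750 lines at 7 years. These values run over the 798 positions, which are not independent replicates. Replicates 1 and 2 of the up-transferred group correlated with 750 lines at 0.961 to 0.965, and replicate 3 with 380 lines at 0.884 to 0.899 and with 750 lines at 0.756 to 0.767. Down-transferred replicates 1 and 2 correlated with 750 lines at 0.908 to 0.932, and replicate 3 with 380 lines at 0.952 to 0.957. At the 12 positions higher in 750 than in 380 lines, among them dnaJ and TERY_RS15250, up-transferred replicates 1 and 2 lay above every 380 library at all 12. Replicate 3 did so at 2, both in dnaJ, and lay below every 380 library at 9.

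**Figure D4:**
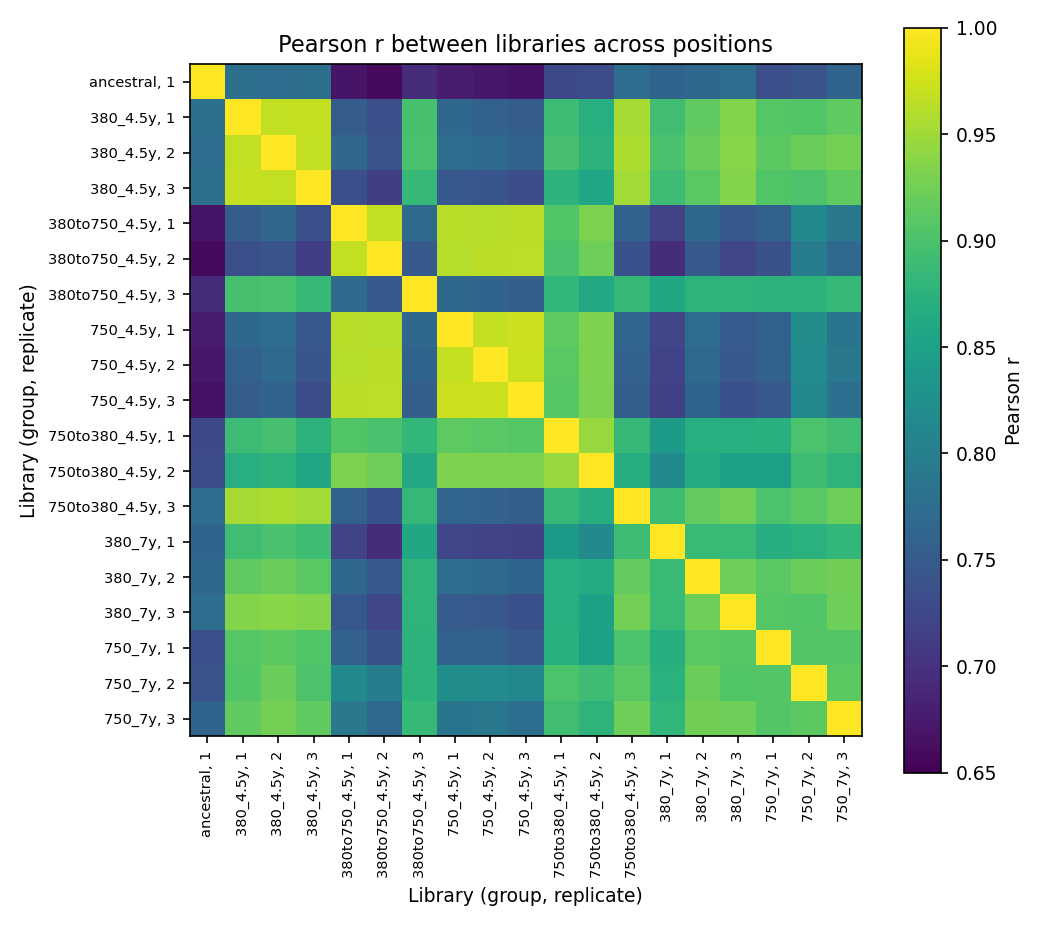
Pearson r between every pair of the 19 libraries across the 798 positions, with libraries by group and replicate on both axes and color from low (dark) to high (bright) r. Up-transferred replicates 1 and 2 form a block with the 750 lines at 4.5 years (r 0.961 to 0.965), and down-transferred replicate 3 joins the 380 lines (r 0.952 to 0.957).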

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

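The tests of technical explanations, the splits of libraries and the interaction of history with current CO2 were chosen only after the results were seen.

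The difference between 750 and 380 lines was not the same at 4.5 and 7 years in 541 positions by the planned interaction test of limma, which is what brought these results here. The largest value was at 5349222 in TERY_RS16665 (62.55 points, adjusted p = 0.00121), the lowest at 4861393 in TERY_RS15250 (-63.66 points, adjusted p = 0.0352, a call that ends without any 1 of 10 of the 12 libraries, adjusted p up to 0.0696) and the one of smallest p at 2669238 in dnaJ (-41.93 points, adjusted p = 0.000476). All 3 libraries of each line were on 1 side at these positions at 4.5 years. Of 100 splits of the libraries, 13 gave as many positions as the real 541 (highest other 774), but the 12 others that did so all kept the 4.5-year grouping of 380 and 750 lines, with at least 607 each. The remaining 87 gave at most 0. This share is set by how many splits keep that grouping, so it does not decide whether chance can be excluded for the interaction.

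The effect of current CO2 differed with selection history in 5 positions by the added interaction test of limma, with 33.17 points at 6089812 in TERY_RS25710 (adjusted p = 0.0468). The others were 3803999 in TERY_RS11790 (30 points), 3806365 in TERY_RS11800 (27.7), 121320 between genes (25.9) and 4999577 in TERY_RS15625 (16.6). Of 100 splits 10 gave as many, so chance cannot be excluded (real 5, highest other 789). Of the 9 others 8 kept the 3 libraries of 380 lines on 1 side, and a split that calls so many more positions points to a structure of the libraries. The count was 764 without replicate 3 of the transferred groups, 504 without up-transferred replicate 3, 660 without down-transferred replicate 3, 0 without any other single library, and 0 on the arcsine scale and after quantile normalisation. With replicate number as a block it was 210, and the splits took no account of these numbers.

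Lower levels at nearly all positions in 750 lines and up-transferred cultures at 4.5 years, with dnaJ and TERY_RS15250 higher, were weighed first. A single shift of whole libraries, such as unequal bisulfite conversion, would keep the order of positions, but the highest Spearman rho between a 380 and a 750 library was 0.823, below the lowest of 0.948 within the groups, so such a shift is argued against as the whole cause, though a shift together with other differences is not. Whether the positions were listed because they differ between 380 and 750 lines cannot be told, since 8 of the 798 were not called and the rule of listing is not given. The labels name no library batch, so a batch that follows CO2 cannot be told apart from it. The difference itself passed the test at 790 positions, a count that listing by this difference would also give. Whether CO2 or such a batch brought the difference about, and how far the listing shaped the count, stays open.

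Replicate 3 of both transferred groups lay nearer the 380 lines than its own group did. An exchange of these 2 libraries is argued against, since down-transferred replicate 3 correlated with up-transferred replicates 1 and 2 at no more than 0.759, where these correlated with each other at 0.968. A mixture of unchanged 380 and 750 cultures is argued against for up-transferred replicate 3, whose residual SD around the best mixture was 6.59 points, above at most 3.51 for left-out libraries of these lines. Whether down-transferred replicate 3 came from a 380 culture that was never moved cannot be told. Its r to a 380 library was 0.957, where the larger SD within its adjacent pairs than in 380 lines allows 0.958. Up-transferred replicate 3 also lay below every 380 library at 9 of the 12 positions higher in 750 lines, where a slower change from 380 towards 750 levels would place it between them. It did lie between them at 178865 in TERY_RS00515 (40.9%), 5349221 in TERY_RS16665 (29.2%), nifD (63.9%) and phnG (26.0%), all lower in 750 lines. Its mean level of 23.8% also lay between those of 380 lines (40.0%) and 750 lines (18.4%). A slower change thus stays open at positions that fell. A difference in pace stays open for down-transferred replicate 3 as well, and neither was tested.

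Levels of 750 lines were higher at 7 than at 4.5 years by 15.7 points in the mean. A shift shared by all libraries of the 7-year sampling is argued against, since the mean of the 380 lines differed by -1.22 points between the years. Whether the 7-year 750 libraries came from 380 cultures cannot be told, because the mean r between the 7-year groups was 0.902, above the lowest r within them of 0.886. A batch of the 4.5-year 750 libraries cannot be told apart from selection, as the labels give none. The change of the 750 lines itself passed the planned test at 664 positions, and what brought it about stays open.

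Comparisons of 3 libraries with 3 allow 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 790 and 0 for 750 against 380 at 4.5 years (1 of 10 as large), 0 and 0 at 7 years (10 of 10), 791 and 7 for the up-transfer (1 of 10), and 41 and 0 for the down-transfer (1 of 10). They were 1 and 0 for the years in 380 lines (1 of 10), 664 and 0 for the years in 750 lines (1 of 10), 656 and 178 for down-transferred cultures against 380 lines (1 of 10), and 0 and 0 for up-transferred cultures against 750 lines (10 of 10). For current CO2, 1 of 100 splits, the real one, gave as many as 795, and for history 4 of 100 gave as many as 98, both shares under 0.05. These shares were not adjusted over comparisons and do not by themselves exclude chance. The highest others were 771 for current CO2, near the ceiling of 798, and 742 for history, where all 3 others as large kept the 380 lines on 1 side. Such counts point to a structure of the libraries, so neither count by itself singles out its own grouping.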

How the results depend on the processing

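The averaging of adjacent positions, the fits without replicate 3 of the transferred groups, and the comparisons of transferred cultures with the lines already at their new CO2 were tests chosen only after the data were seen. No coverage minimum could be tried, because no depth is held. Of 2649 values of named positions under an alternative, 2318 kept their direction and side of the threshold, 312 lost their call, 15 gained one and 4 turned direction, all in rplE. These values cover positions named by the rule, and other list positions also turned direction after quantile normalisation. For the dnaJ positions in 750 against 380 lines at 4.5 years direction and side held in 28 of 28 values. Of 98 mean-level values 94 kept direction and side and 4 turned direction. Except where said, the cause of these changes was not tested.

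Quantile normalisation, which by its construction removes shifts of whole libraries, gave 125 calls for 750 against 380 at 4.5 years, 9 for the up-transfer, 12 for the down-transfer, 153 for the years in 750 lines, 0 for history, 108 for current CO2, 15 for the interaction of CO2 with year, 1 for down-transferred cultures against 380 lines, 1 for up-transferred cultures against 750 lines and 0 for the interaction of history with current CO2. With it rplE 4652171 turned direction for 750 against 380 at 4.5 years (0.713 points), the up-transfer (2.67), the years in 750 lines (-1.74) and current CO2 (2.25).

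For 750 against 380 at 7 years the log2 ratio gave 1 call, the libraries of the comparison only 2 and averaged adjacent positions 1. For the down-transfer (41 calls) the count was 248 with the arcsine, 289 with the log2 ratio, 84 with mean levels of 10 to 90 percent, 96 with the libraries of the comparison only, 2 with no trend, 141 with averaged positions and 23 without replicate 3 of the transferred groups. For the years in 380 lines the libraries of the comparison only gave 5. For history (98 calls) the arcsine, log2 ratio and fit with no trend gave 0, a difference of at least 10 points 54, averaged positions 149 and the fit without replicate 3 569. Up-transferred cultures against 750 lines gave 1 without replicate 3, and the median over positions turned their mean-level difference to 0.551. For the interaction of history with current CO2 (5 calls) the arcsine and the libraries of the comparison only gave 0, no trend 77, averaged positions 151 and the fit without replicate 3 764. Replicate number as a block gave 281 for the down-transfer (222 by line), 3 for the years in 380 lines (3 by line), 329 for history and 210 for history with current CO2. Libraries of the same number deviated together, with every r over 0.1, in 1 of 15 pairs of groups, the transferred groups (r 0.178, 0.436 and 0.528), so the numbers were not taken as pairs in comparisons with the other groups. However, 11 of 18 libraries were closest to their own number, above the 1 in 3 expected without pairing. A shared effect of the numbers is therefore not excluded, and the block counts remain an open alternative.

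Leaving out 1 library at a time, the counts ranged from 776 to 783 for 750 against 380 at 4.5 years, 0 to 3 at 7 years (1 without 380-line replicate 2 or 3, 3 without 750-line replicate 3), 780 to 797 for the up-transfer, 0 to 300 for the down-transfer, 1 to 2 for the years in 380 lines, 548 to 644 for the years in 750 lines, 0 to 634 for history, 791 to 795 for current CO2, 360 to 554 for the interaction of CO2 with year, 12 to 776 for down-transferred cultures against 380 lines, 0 to 0 for up-transferred cultures against 750 lines and 0 to 660 for history with current CO2. The mean-level difference of the years in 380 lines ranged from -2.48 without 7-year replicate 3 to 0.163 without 7-year replicate 2, and that of up-transferred cultures against 750 lines from -2.92 without up-transferred replicate 3 to 0.896 without replicate 1 and 1.5 without replicate 2. The correlation of CO2 differences between years ranged from 0.147 without 7-year 750 replicate 2 to 0.309 (permutation p = 0.03) without 7-year 750 replicate 1, and was 0.263 (permutation p = 0.04) without 4.5-year 750 replicate 1.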

Other observations

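Of the tests in this part, those on adjacent positions and on positions per gene were chosen only after the result was seen, and the test on positions of the same gene was written before.

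The listed positions were gathered in some genes, most of all in the pseudogene TERY_RS25240 with 19 positions. Its mean level was 60% in the ancestral library, 33.4% ± 2.13 (SD, n = 3) in 380 lines, 8.94% ± 7.98 in up-transferred cultures, 6.37% ± 0.497 in 750 lines and 18.8% ± 9.45 in down-transferred cultures at 4.5 years, and 32.1% ± 2.72 in 380 lines and 27.2% ± 3.35 in 750 lines at 7 years. TERY_RS25725, TERY_RS24065, TERY_RS18870 and TERY_RS22955 followed with 8 positions each. In TERY_RS25725 the level was 39.7% ± 1.2 in 380 lines and 11.1% ± 0.474 in 750 lines at 4.5 years, and in TERY_RS22955 48.1% ± 2.27 and 22.9% ± 1.03. These genes were named after their values were seen.

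Adjacent positions differed in level in the same direction across libraries. In TERY_RS01265, 425383 averaged 29.2% and 425384 47.1%, with the second higher in 18 of 18 libraries. In TERY_RS01770, 589473 averaged 51.2% and 589474 34.8%, in TERY_RS24690, 1095023 averaged 15.4% and 1095024 30.9%, and in TERY_RS11215, 3641123 averaged 45.4% and 3641124 30%, each in 1 direction in 18 of 18 libraries. Such a direction in all 18 libraries was found in 32 of the 212 pairs.

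A hypothesis was that each pair of adjacent positions has a difference of its own that libraries share. The mean r of pair differences between libraries of different groups was 0.559, and the highest of 1000 shuffles of the pairs gave 0.0179 (permutation p = 0.001, the smallest they can give). This may reflect unequal methylation of the 2 strands or a bias of the sequence around each position, which could not be told apart without strand and sequence.

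A further hypothesis was that positions of the same gene that are not adjacent change together between 750 and 380 lines at 4.5 years. The mean product of their standardised differences was 0.151 over 286 pairs of loci, above 0.0919, the bound of 95% of 10000 shuffles (permutation p = 0.0114). Without TERY_RS25240 it was 0.147 over 220 pairs (permutation p = 0.0176). Genes with at least 4 listed loci numbered 14, where 1000 random placements over gene sequence gave 0.909 on average and at most 4 (permutation p = 0.001, the smallest they can give). The gene with most loci had 12, where placements gave at most 10. The listing rule may have produced this gathering, since it is not given.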
